A study of Mus musculus with 8 samples.

How the data were processed

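RNA from about 200 sorted splenic B cells per library was reverse transcribed with an oligo-dT primer and a template-switching oligo and amplified with 17 PCR cycles, per the labels' protocols, with 5 mice used in each experiment. Groups and replicate numbers came from the sample titles: 4 Uninduced and 4 Induced libraries, which differ by the control or the Zfp318 form of 1 named allele in the genotype. Trim Galore 0.6.6, STAR 2.2.0, featureCounts and the build mm10 are named in the submitters' processing notes, without roles or settings. The authors deposited 1 table with a normalized signal per gene and library, which its name describes as coding-sequence counts; the factor used for normalization is not given in the sources used here. Nor is it given whether strand was used, so overlapping and antisense genes cannot be told apart.

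In each library every deposited value was a whole multiple of 1 step, so whole reads were recovered by dividing by that step (100% of values within 0.05 of a whole number in every library). Totals of recovered reads ran from 6788934 to 24567248 per library, and normalized totals from 1312929 to 1511945. Reads carry no molecular identifiers, so intervals and floors of 3 reads cover counting error only. The table held 22680 entries, of which 13478 had a value above 0 in any library. Of the 22680 entries 27 carried symbols turned into dates by a spreadsheet, which were kept in the tests but not named under the rule. Coordinates came from GENCODE M21 by symbol (20140 symbols, and 240 more by synonym), and GC content and coding length were known for 7129 of the tested genes.

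The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), for the 7316 genes with a mean of at least 10 over the 8 libraries, with a trended and robust prior, two-sided, and Benjamini-Hochberg adjusted p below 0.05. Gene lists, 51 in number and fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were measured (45 lists), beside camera with an estimated correlation and fry. The last tests whether the genes of a list move 1 way on balance and does not compare a list with other genes. Zfp318 was also tested with an exact permutation test over all 70 orderings. The design, the alternatives and the rule for named genes were fixed before the data were examined.

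The rule first named Zfp318. It then named the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold with groups that did not overlap and a mean of at least 50 in the higher group. For each described list it named up to 4 members with the smallest p, and the 2 with the highest means where none passed. Members that did not pass are given only for the mtDNA-encoded list and for lists without a passing member. It always named, as values, Ighd, Ighm, Bcl2, Bcl6, Prdm1, Cd38, Tfam, Ppargc1a and Myc, and 1 more gene that is not reported here. Predicted genes, pseudogenes and immunoglobulin variable segments were counted but not named. Named outside the rule, after their values were seen, were Ighg1, Iglc1, Mzb1, Derl3, the date-form symbol 4-Sep, Hsf5, the CD3, T cell receptor segment and Y-linked genes.

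Alternatives were the replicate number as a block, pseudocounts of 0.5 and 5, no filter and a mean of at least 50, equal totals, median ratio and upper quartile scaling, immunoglobulin genes left out, limma without the robust option or with array weights, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, a threshold of 0.1, and leaving out each library in turn. Both count tools take the reads as recovered. A fit with a smooth trend of GC content and coding length removed per library was added after seeing the data. The tests were checked on simulated counts for the comparison of Induced with Uninduced: limma on 7306 genes called 6 of 67 genes changed 1.5-fold, 34 of 67 changed 2-fold and 58 of 66 changed 4-fold, and 4 of its 102 calls were false. Camera called 20 of 20 simulated lists of 20 members changed 1.3-fold and 0 of 20 unchanged lists, which were drawn without correlation between genes.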

Results

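Splenic memory B cells that bound the hapten NP were compared between libraries labelled Induced and Uninduced for Zfp318. The title of the series ties this zinc finger gene to mitochondrial function and to recall. The cells carried B1-8hi, a heavy chain allele that binds NP. They were sorted as tdTomato-positive cells without CD138, GL7 or FAS and with B220 and CD38. The spleens were taken 7 days after immunization with NP coupled to ovalbumin in LPS and alum, and about 200 cells went into each library. Each group held 4 libraries. The reads recovered from the deposited values came to 6788934, 24567248, 17017568 and 23724613 in Uninduced replicates 1 to 4. They came to 11957766, 11462109, 14937093 and 15727509 in Induced replicates 1 to 4. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. All values below are normalized read counts over coding sequence, given as mean ± SD with n = 4 per group. Log2 fold changes are Induced minus Uninduced on the scale of log2(value + 1), which understates the change of low genes.

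The first comparison asked whether the labelled gene was higher in the Induced libraries. Zfp318 (chromosome 17, 46383731 to 46420920, mm10) measured 17.7 ± 6.91 (SD, n = 4) in Induced and 4.65 ± 3.18 (SD, n = 4) in Uninduced libraries, a ratio of means of 3.79. Every Induced library, from 9.57 to 25.3, lay above every Uninduced library, from 1.25 to 8.18. An exact two-sided permutation test over 70 orderings gave p = 0.0286, the smallest p this design allows. In limma's fit over all genes its log2 fold change was 1.84 (SE 0.52), which did not pass the threshold (adjusted p = 0.0707). The level was low in both groups, with 14 to 111 reads per Uninduced library and 98 to 202 per Induced library.

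**Figure D1:**
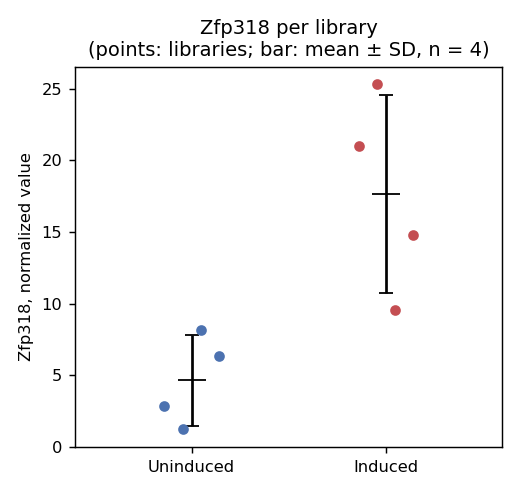
Normalized value of Zfp318 on the vertical axis for each of the 8 libraries, by group; points are libraries and bars are the mean ± SD. The 4 Induced libraries sit between 9.57 and 25.3, all above the Uninduced libraries.

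The second comparison asked which genes differed between the groups. Constant-region genes of the T cell receptor rose most in limma's fit. Trac (chromosome 14, 54220521 to 54224206), the alpha chain constant region, went from 1.60 ± 1.85 to 7408 ± 2241 (log2 fold change 11.65, adjusted p = 2.4e-07). Trbc2 (chromosome 6, 41546730 to 41548352), a beta chain constant region, had no read in any Uninduced library and measured 253 ± 40.1 in Induced libraries. This was at least 4530-fold higher than the floor of 3 reads over the Uninduced group. Rnf43 (chromosome 11, 87662722 to 87735539), a ubiquitin ligase that acts on Wnt receptors, went from 0.627 ± 0.597 to 191 ± 39.4 (adjusted p = 3.2e-11). Supt4a (chromosome 11, 87737552 to 87743623), a subunit of a transcription elongation factor, rose from 302 ± 28.5 to 584 ± 58.9 (adjusted p = 0.000234). Mtmr4 (chromosome 11, 87592162 to 87616302), a phosphoinositide phosphatase, rose from 25.1 ± 10.7 to 60.4 ± 17.5 (adjusted p = 0.0323). The Mtmr4 call held in 3 of the 8 fits that left out 1 library.

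The other genes named among the largest rises had log2 fold changes from 0.97 to 1.31. Necap2, which takes part in clathrin-coated vesicle transport, rose from 49.1 ± 13.3 to 121 ± 18.6, and the histone chaperone Asf1b from 82.5 ± 11.6 to 183 ± 57.3. The endoplasmic reticulum protein gene Sdf2l1 rose from 194 ± 51.5 to 379 ± 64.1, and the mitochondrial isocitrate dehydrogenase gene Idh2 from 71.0 ± 15.3 to 140 ± 27.0. The others were Rnf121 (28.6 ± 13.6 to 61.8 ± 12.8), the RNA methyltransferase gene Nsun5 (29.5 ± 6.44 to 62.2 ± 9.50) and Tmem214 (59.1 ± 4.57 to 123 ± 30.6). In limma's fit their adjusted p ranged from 0.00382 for Necap2 to 0.0398 for Rnf121. Of the 8 fits that left out 1 library, Necap2, Asf1b and Sdf2l1 were called in all 8. Tmem214 was called in 7, Idh2 in 5, Nsun5 in 4 and Rnf121 in 2.

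Among the named genes that fell past the threshold, the largest change was in mt-Nd6 (chromosome M, 13552 to 14070), a complex I subunit encoded in mitochondrial DNA. It went from 151 ± 66.8 to 48.8 ± 12.2 (log2 fold change -1.54, limma adjusted p = 0.0101). The complement regulator Cd55 fell from 60.0 ± 4.70 to 27.2 ± 11.7, the egress receptor S1pr1 from 69.5 ± 13.0 to 34.4 ± 7.02, and the complement receptor Cr2 from 203 ± 37.0 to 115 ± 29.1. U2surp fell from 132 ± 29.8 to 76.2 ± 17.8, the splicing kinase gene Clk1 from 240 ± 62.0 to 140 ± 29.5 and Luc7l3 from 108 ± 10.5 to 65.0 ± 10.9. The interferon-inducible gene Mndal fell from 87.7 ± 24.1 to 34.96 ± 11.04, Ogfrl1 from 76.0 ± 9.93 to 40.02 ± 9.49, and Plac8 from 242 ± 29.2 to 150 ± 28.3. The ribosomal protein gene Rpl39 fell from 829 ± 106 to 499 ± 97.7, and Rpl22l1, a paralog of Rpl22, from 268 ± 82.0 to 160 ± 23.8. Adjusted p for these 11 genes after mt-Nd6 ranged from 0.0127 to 0.0490. Of the 8 fits that left out 1 library, mt-Nd6 and Rpl39 were called in all 8, and Mndal and Cr2 in 4. Clk1, Ogfrl1 and Plac8 were called in 3, S1pr1 and Rpl22l1 in 2, and Cd55, U2surp and Luc7l3 in only 1.

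In all, 142 of 7316 genes passed limma's threshold of adjusted p below 0.05, 99 of them higher and 43 lower in Induced libraries. The groups did not overlap for 725 genes, or 9.91%. Chance gives 2.86% on average over orderings, but genes vary together, so the excess is not a test. The split between higher and lower calls moved with the scaling. With every library brought to the same total, which shifted the median log2 fold change of all genes from 0.03 to -0.08, 60 genes were higher and 96 lower. Scaling to the upper quartile gave 69 and 69, and leaving out immunoglobulin genes gave 69 and 88. Fold changes followed GC content across genes, which are not independent replicates (Spearman's rho 0.355 over 7129 genes). The count fell to 71 (38 higher, 33 lower) after a trend with GC content and coding length was removed, an alternative chosen after seeing the data. It fell to 32 with edgeR on recovered reads, which tested 10246 genes, and to between 29 and 75 without 1 of Uninduced replicates 2 to 4 or Induced replicates 2 to 4, and rose to 283 without Induced replicate 1. It also rose to 399 with DESeq2 on recovered reads, which tested 12523 genes, and to 255 with array weights.

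The third comparison asked whether gene lists fixed beforehand moved. Of 45 lists with enough measured genes, 20 passed camera's threshold with its preset correlation, 12 higher and 8 lower. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.283 and 4 lists had an unadjusted p below 0.05. The test fry passed 2 lists, T cell and Quiescence factors. The other 25 lists had camera adjusted p from 0.0624 to 0.919.

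Mitochondrial lists moved in both directions. The mtDNA-encoded list was lower (median log2 fold change -1.02, camera adjusted p = 6.2e-10, adjusted p = 0.283 with an estimated correlation). All 9 measured members had negative log2 fold changes, 1 of them past the threshold over all genes and 5 adjusted over the list alone. Besides mt-Nd6, the members with the smallest p were mt-Co2 (28.2 ± 11.6 and 10.2 ± 5.46), mt-Nd2 (211 ± 126 and 69.5 ± 20.8) and mt-Nd4 (1555 ± 449 and 969 ± 189), in Uninduced and Induced libraries. Uninduced means of the 9 members ran from 28.2 for mt-Co2 to 3834 for mt-Cytb. Whether reads were lost for the low members was not tested, so the values may not reflect transcript levels. The gene mt-Nd6 lies on the minus strand, and whether strand was used is not given, so antisense reads cannot be told apart. The mtDNA-encoded share of the library total was 0.812 ± 0.348% in Uninduced and 0.396 ± 0.109% in Induced libraries, which overlapped (exact two-sided permutation p = 0.0571, n = 4). Uninduced replicate 1, at 0.449%, lay among the Induced libraries, and Induced replicate 2 was at 0.233% against 0.442 to 0.464% in the others. With the trend with GC content and coding length removed, the list's median was -0.40 and mt-Nd4 was at 0.13.

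The nuclear lists for the TCA cycle, Complexes II and III and Complex I were called higher. In the TCA cycle list 4 of 20 measured members rose and none fell (7 rose adjusted over the list alone; camera adjusted p = 6.2e-05, adjusted p = 0.337 with an estimated correlation). They were Idh2, malate dehydrogenase Mdh2 (602 ± 72.0 to 931 ± 116), the isocitrate dehydrogenase subunit Idh3g (475 ± 54.9 to 703 ± 33.4) and citrate synthase Cs (191 ± 22.3 to 298 ± 42.3). Of 13 measured genes of Complexes II and III only Sdhb, a succinate dehydrogenase subunit, passed (728 ± 15.5 to 990 ± 70.5), with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00862, adjusted p = 0.283 with an estimated correlation, and 0.0745 at a mean of at least 50). Of 36 measured Complex I genes only Ndufs8 passed (862 ± 102 to 1266 ± 132), with 5 higher adjusted over the list alone (camera adjusted p = 0.0189, adjusted p = 0.546 with an estimated correlation). This call was lost under each other scaling, such as equal totals (adjusted p = 0.198), and with the GC trend removed (adjusted p = 0.622), and also without Uninduced replicate 2 (0.258) or Induced replicate 2 (0.0683). In the ATP synthase list, which did not pass (camera adjusted p = 0.0624) but did with the GC trend removed (adjusted p = 0.0437), Atp5d (572 ± 50.5 to 831 ± 80.8) and Atp5b (1495 ± 47.8 to 2098.5 ± 278) rose and Usmg5 fell (272 ± 43.2 to 177 ± 24.6). Adjusted over the list alone, 4 of its 16 measured members were higher and 1 lower. The lists for Complex IV (camera adjusted p = 0.208), the mitochondrial ribosome (0.106), fatty acid oxidation (0.134), mitochondrial import (0.257), mitochondrial genome maintenance (0.456) and mitochondrial dynamics (0.919) did not pass.

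Lists of glycolysis, antioxidant and protein folding genes were called higher in Induced libraries, with 2 or 3 members of each past the threshold. In the Glycolysis list 3 of 15 measured members rose and none fell (9 rose adjusted over the list alone; median log2 fold change 0.46, camera adjusted p = 3.5e-06, adjusted p = 0.283 with an estimated correlation). They were pyruvate kinase Pkm (428 ± 91.8 to 718 ± 140), enolase Eno1 (713 ± 35.7 to 1000.4 ± 164) and phosphoglycerate mutase Pgam1 (53.5 ± 9.94 to 104 ± 31.9). In the Antioxidant defence list 3 of 19 rose (6 adjusted over the list alone; camera adjusted p = 0.000137, adjusted p = 0.283 with an estimated correlation). They were mitochondrial thioredoxin Txn2 (160 ± 13.7 to 265 ± 36.5), the glutathione peroxidase Gpx4 (210 ± 35.3 to 326 ± 46.1) and superoxide dismutase Sod1 (861 ± 75.1 to 1151 ± 33.1). In the Unfolded protein response list 2 of 23 rose, Sdf2l1 and the chaperone Hspa5 (454 ± 18.0 to 677 ± 79.4), and 5 adjusted over the list alone (camera adjusted p = 0.00017, adjusted p = 0.337 with an estimated correlation). In the Plasma cell list, which did not pass (camera adjusted p = 0.362), 2 of 22 rose, Mzb1 (2229 ± 320.1 to 3350.5 ± 221) and Derl3 (132 ± 26.2 to 231 ± 52.7), in limma's fit with adjusted p = 0.00477 and 0.0278. Both act in the endoplasmic reticulum, were named after their values were seen, and 4 members were higher and 4 lower adjusted over the list alone. In the Integrated stress response list 1 of 15 rose, the serine synthesis enzyme Phgdh (347 ± 35.7 to 590 ± 60.4, adjusted p = 0.0025), and 3 adjusted over the list alone (camera adjusted p = 0.0415, adjusted p = 0.495 with an estimated correlation). This call was lost with equal totals (adjusted p = 0.0542) and with the GC trend removed (adjusted p = 0.178). It was also lost without Uninduced replicate 2 (0.0569) or 4 (0.174), or Induced replicate 1 (0.0532), 3 (0.0514) or 4 (0.179).

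The S phase list of DNA replication genes was called higher as well. Of its 41 measured members 4 rose and none fell (11 rose adjusted over the list alone; median log2 fold change 0.26, camera adjusted p = 6.4e-05, adjusted p = 0.495 with an estimated correlation). These were the replicative helicase subunits Mcm2 (186 ± 24.3 to 326 ± 74.1), Mcm3 (261 ± 28.9 to 411 ± 100.4) and Mcm5 (352 ± 38.6 to 557 ± 126), and the flap endonuclease Fen1 (88.9 ± 10.0 to 168 ± 48.1). Relative to all tested genes, the S phase list's mean log2 value overlapped between the groups. Induced replicate 1 was at 1.14, while Uninduced replicates 1 and 4 were at 1.17. The G2 and M phase list did not pass (camera adjusted p = 0.919, median log2 fold change -0.00) but was called higher with the GC trend removed (median 0.16, adjusted p = 0.0208).

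Lists of follicular and naive B cells, memory B cells and quiescence factors were called lower. In the Follicular and naive B cell list Cr2, S1pr1 and Cd55 fell and the BAFF receptor gene Tnfrsf13c rose (347 ± 54.6 to 552 ± 117). The list had 7 lower and 1 higher of 20 adjusted over the list alone (median log2 fold change -0.31, camera adjusted p = 0.000337, adjusted p = 0.283 with an estimated correlation). In the Memory B cell list 2 of 22 fell, Mndal and Cr2, with 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00114, adjusted p = 0.283 with an estimated correlation). The higher one was Zfp318. In the Quiescence factors list S1pr1 fell and the cell cycle inhibitor gene Cdkn2d rose (90.1 ± 15.4 to 154 ± 32.6). Of 18 measured members 3 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.283 with an estimated correlation, and 0.112 at a mean of at least 50). The Immediate early and NR4A list, of genes induced by activation, was also called lower (camera adjusted p = 0.0449, adjusted p = 0.449 with an estimated correlation). This call was lost with equal totals (adjusted p = 0.0542) and held with the GC trend removed (adjusted p = 5.84e-05). It was also lost without Uninduced replicate 1 (0.0976) or 3 (0.243), or Induced replicate 1 (0.0896), 3 (0.163) or 4 (0.128). None of its 19 measured members passed over all genes or adjusted over the list alone. Zfp36l1 measured 1748 ± 233 and 1465 ± 131 in Uninduced and Induced libraries, Nfkbia 932 ± 75.5 and 841 ± 115, Nr4a1 37.2 ± 30.0 and 14.5 ± 5.86, and Dusp1 55.8 ± 19.4 and 34.5 ± 10.8. Jun went the other way, with 17.2 ± 10.7 and 27.6 ± 10.9.

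The MHC class II and co-stimulation list had 2 of 19 members higher, the invariant chain Cd74 (20564 ± 1355 to 29617 ± 4206) and H2-Ab1 (11093 ± 519 to 14598 ± 1297). It had 4 higher adjusted over the list alone (camera adjusted p = 0.0369, adjusted p = 0.590 with an estimated correlation). The MHC class I presentation list had 1 of 17 higher, H2-D1 (1640.2 ± 113 to 2212 ± 309), a gene with near-identical relatives whose reads could be split. It had 3 higher adjusted over the list alone (camera adjusted p = 0.0369, adjusted p = 0.495 with an estimated correlation). Both calls were lost with equal totals (adjusted p = 0.143 and 0.188) and with the GC trend removed (adjusted p = 0.871 for both). The class II call was also lost without Uninduced replicate 1 (0.0923) or Induced replicate 3 (0.126) or 4 (0.128). The class I call was lost without Uninduced replicate 3 (0.0788) or 4 (0.0579), or Induced replicate 3 (0.0911) or 4 (0.0514).

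The lists of ribosomal protein and splicing genes were called lower, though 14 of 45 large-subunit, 12 of 33 small-subunit and 10 of 32 splicing genes had positive log2 fold changes. Of 45 measured large-subunit genes 9 fell and none rose, with 15 lower and 2 higher adjusted over the list alone (camera adjusted p = 2.6e-05, adjusted p = 0.283 with an estimated correlation). Rpl35a went from 1702 ± 101 to 1214 ± 99.7, Rpl23a from 2453 ± 36.9 to 1788 ± 172, and Rpl22 from 1072 ± 85.9 to 777 ± 39.9. Of 33 small-subunit genes 3 fell, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00358, adjusted p = 0.439 with an estimated correlation, and 0.0923 without Uninduced replicate 1). They were Rps24 (3774 ± 178 to 2617 ± 124), Rps20 (4308 ± 364 to 3270 ± 196) and Rps27 (9299 ± 406 to 7632 ± 311). Ribosomal protein genes have many pseudogene copies, so reads could be split between them. In the Splicing and transcription elongation list 2 of 32 fell, Son (1118 ± 29.6 to 814 ± 60.7) and Rbm39 (440.1 ± 35.4 to 295 ± 60.0). The list had 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00351, adjusted p = 0.283 with an estimated correlation).

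**Figure D2:**
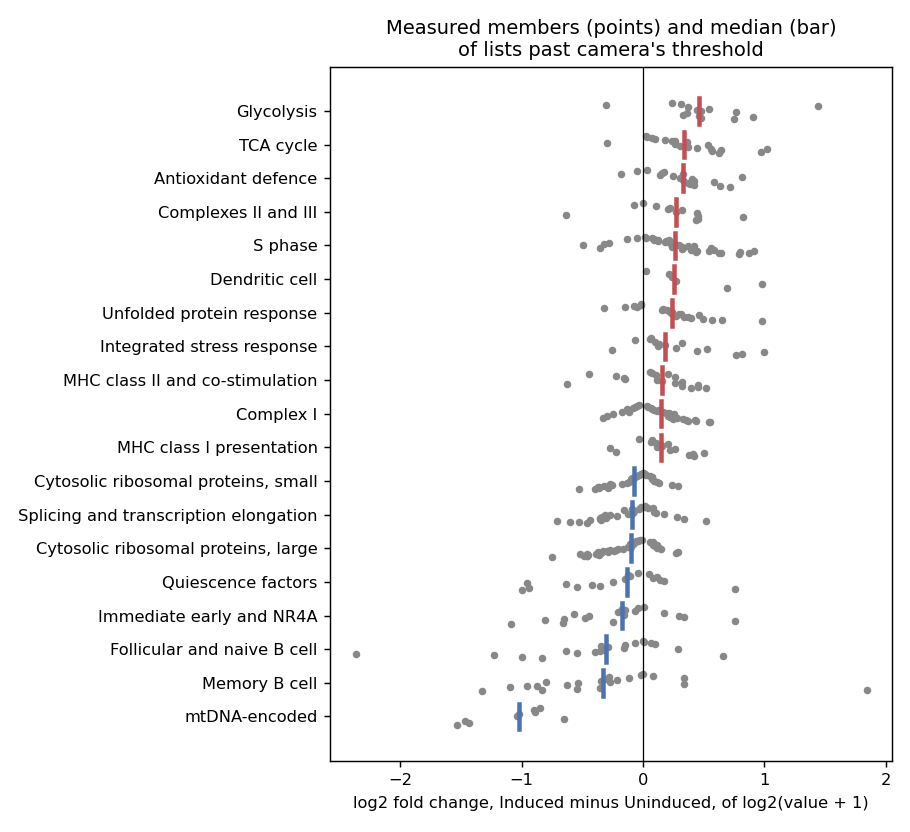
Log2 fold change (Induced minus Uninduced) on the horizontal axis for each measured member (points) of 19 of the 20 lists past camera's threshold, T cell left out for its range, with the list's median as a bar (red for lists called higher, blue for lower). The mtDNA-encoded list lies farthest left with a median of -1.02 and Glycolysis farthest right with 0.46.

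Markers of other cells were summed as CPM of each library's normalized total. The gate, without CD138, GL7 or FAS and with B220, selects against plasma cells, germinal centre cells and most cells outside the B lineage. How fully it did so is not shown by these sums. The T cell sum was 263 ± 37.3 in Uninduced and 5470 ± 1420 in Induced libraries. Without the receptor genes it was 262 ± 36.1 and 219 ± 12.3, most of it Cd2. The CD3 chain genes Cd3d, Cd3e and Cd3g together came to at most 0.0257% of Trac in the Induced libraries. In the T cell list 2 of 5 measured members rose, Trac and Trbc2, over all genes and adjusted over the list alone (camera adjusted p = 0.000137, adjusted p = 0.283 with an estimated correlation). The list's mean was 3.84, while its median log2 fold change was 0.00 and negative under each other scaling. The Plasma cell sum was 4890 ± 439 and 5930 ± 649, and the Germinal centre B cell sum 4380 ± 325 and 4540 ± 216. The Monocyte and macrophage sum was 135 ± 19.5 and 143 ± 13.9, and the Dendritic cell sum 2000 ± 169 and 2170 ± 109. The sums for NK cells (10.5 ± 3.56 and 13.9 ± 4.73), neutrophils (1.00 ± 1.14 and 0.388 ± 0.552), erythroid cells and platelets (61.1 ± 15.5 and 60.4 ± 5.68) and stromal cells (43.5 ± 8.44 and 50.8 ± 13.7) were low. The sums are given as values: the smallest exact permutation p here is 0.0286, with which 1 sum of 10 cannot pass after adjustment. The Dendritic cell list passed camera (adjusted p = 0.0128, adjusted p = 0.283 with an estimated correlation, 0.154 with the GC trend removed and 0.150 at a mean of at least 50) with no member past the threshold and 3 higher adjusted over the list alone. Its members with the smallest p were Bst2 (83.7 ± 17.9 and 135 ± 25.1) and Fscn1 (28.3 ± 9.20 and 62.03 ± 33.5). Those with the highest means, Ly6d (1277 ± 171 and 1503 ± 142) and Cst3 (626 ± 61.1 and 755 ± 16.8), are also expressed in B cells.

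**Figure D3:**
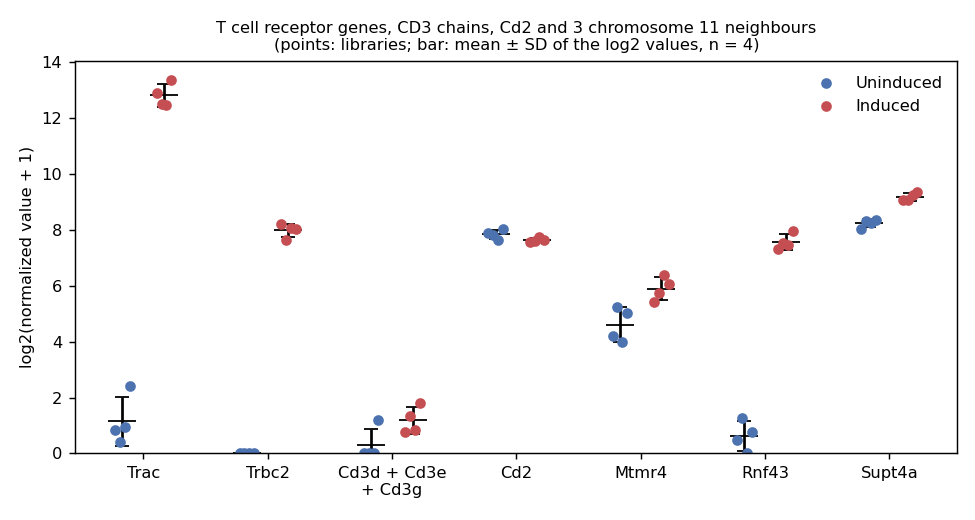
Values as log2(normalized value + 1) on the vertical axis for Trac, Trbc2, the sum of the CD3 chain genes, Cd2 and 3 neighbouring genes of chromosome 11; points are libraries and bars the mean ± SD of the log2 values. Trac and Trbc2 are high in all 4 Induced libraries, while the CD3 sum stays near 0 in both groups.

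Genes fixed for their role in B cell fate and mitochondria gave the following values in Uninduced and Induced libraries, none past the threshold in limma's fit. Ighd measured 43.8 ± 41.2 and 6.99 ± 6.51 (adjusted p = 0.0696), and Ighm 5517 ± 4816 and 5543 ± 2314. Ighd passed with the replicate number as a block (adjusted p = 0.0114), with DESeq2 (0.0408), and without Uninduced replicate 1 (0.026) or Induced replicate 4 (0.0408). The plasma cell regulator Prdm1 measured 43.2 ± 7.26 and 23.8 ± 17.7, and the germinal centre regulator Bcl6 922 ± 89.5 and 923 ± 16.7. Prdm1 passed without Induced replicate 1 (adjusted p = 0.0113). Cd38 measured 51.8 ± 11.4 and 42.5 ± 8.36, the survival gene Bcl2 35.02 ± 12.8 and 23.7 ± 9.07, and Myc 156 ± 24.4 and 199 ± 66.1. Tfam, which packages mitochondrial DNA and takes part in its transcription, measured 36.9 ± 8.88 and 34.6 ± 8.88. Ppargc1a, a coactivator of mitochondrial biogenesis, had no read in any library, below a floor of 0.0559 in Uninduced and 0.0808 in Induced libraries (3 reads over the group).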

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

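The rule for a library that stands apart was fixed before the values were seen, and Ighg1, Iglc1, Mzb1 and Derl3 were added to the genes checked after their values were seen. In a group of 4 libraries, the gap between an extreme library and its nearest neighbour, as a share of the group's range, had to exceed Dixon's 95% critical value. Of 188 groups checked, 15 met it, and chance alone gives about 1 in 20. No explanation was tested for these values.

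Several of them were in Induced replicate 2: Mndal at 18.4 (the others 39.5 to 41.1), Rpl39 at 353 (533 to 560), Rbm39 at 205 (314 to 335) and the mtDNA-encoded share of the total at 0.233% (0.442 to 0.464%). Uninduced replicate 4 stood apart for Trac at 4.36 (0.327 to 0.926), Rpl39 at 986 (761 to 790), Rpl22l1 at 390 (218 to 237) and the Dendritic cell marker sum at 1750 CPM (2060 to 2120). Uninduced replicate 3 stood apart for Cd38 at 34.9 (55.7 to 59.7) and Fen1 at 74.0 (92.7 to 95.5). Induced replicate 1 stood apart for Nr4a1 at 23.2 (11.03 to 12.5), Rpl22 at 836 (754 to 760) and Iglc1 at 73800 (50700 to 54500). The remaining ones were Sod1 at 1200 (1130 to 1140) in Induced replicate 3, and the Monocyte and macrophage marker sum at 164 CPM (121 to 128) in Uninduced replicate 1.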

How the results depend on the processing

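The GC content and coding length alternative was chosen after seeing the data; the others were planned. Against 142 genes (99 higher, 43 lower), the counts were 15 (13, 2) without a filter, where more genes were tested, and 215 (161, 54) at a mean of at least 50, where fewer were. They were 255 (187, 68) with array weights, 110 (83, 27) without the robust option, 32 (27, 5) with edgeR, which tested 10246 genes against 7316, 399 (252, 147) with DESeq2 on 12523 genes, 71 (38, 33) with the GC content and coding length trend removed, and 306 (213, 93) at adjusted p below 0.1. Equal totals gave 60 higher and 96 lower, the upper quartile 69 and 69, and leaving out immunoglobulin genes 69 and 88. Except for the looser threshold, the cause was not tested. Leaving out 1 library gave 29 to 283 genes (23 to 211 higher, 6 to 72 lower): 29 without Induced replicate 2, 39 without Uninduced replicate 3, 49 without Induced replicate 4, 53 without Induced replicate 3, 72 without Uninduced replicate 4, 75 without Uninduced replicate 2, 147 without Uninduced replicate 1 and 283 without Induced replicate 1.

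Of the 61 named genes past the threshold, none changed direction under any setting. That is little test, since they were chosen in these same libraries. Where the groups did not overlap, leaving out 1 library could not reverse the sign. Under all settings that tested these genes, 6 of the 61 were called (Trac, Trbc2, Rnf43, Supt4a, Phgdh and Rps24). Without each library in turn 14 were called, with edgeR 14, with DESeq2 60 and with the GC trend removed 25. Zfp318 had log2 fold changes from 1.24 to 2.14 and never passed 0.05, though DESeq2 gave it no adjusted p and limma's 0.0707 passes 0.1; at a mean of at least 50, and without Induced replicate 1 or 2, it fell below the filter. Lists past the threshold went from 20 to 11 at a mean of at least 50 (Complexes II and III at 0.0745, Quiescence factors at 0.112), to 0 with an estimated correlation and to 2 with fry, and ranged from 16 to 21 without 1 library; 11 of the 20 passed under every setting with the preset correlation that tested them (T cell was not tested at a mean of at least 50 or with DESeq2). Leaving out 1 library ended the calls for Immediate early and NR4A, MHC class II and co-stimulation, MHC class I presentation, the small ribosomal subunit, Complex I and Integrated stress response, with values in the report. Of the named genes that had not passed, some did under other settings, with the direction kept: mt-Nd2 under 7, Ighd, Bst2 and mt-Co2 under 4 each, mt-Nd4 and Fscn1 under 2 each, and Prdm1 and Zfp36l1 under 1 each. Some genes that had not passed changed sign. Bcl6 went to -0.10 with equal totals, -0.02 with the median ratio, -0.07 with the upper quartile, -0.09 without immunoglobulin genes, -0.01 with array weights, -0.02 with edgeR, -0.01 with DESeq2, -0.06 with the GC trend removed, and from -0.04 to 0.06 without 1 library, below 0 without Uninduced replicate 1 (-0.02) or 3 (-0.04) or Induced replicate 1 (-0.00). Ighm went to -0.05 with edgeR and with DESeq2, and mt-Nd4 to 0.13 with the GC trend removed. Tfam went to 0.01 with the GC trend removed and from -0.25 to 0.03 without 1 library, above 0 without Uninduced replicate 4 (0.03) or Induced replicate 1 (0.00). The cause was not tested.

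Same-numbered libraries of the groups shared only a number. The correlations of their deviations were -0.0839, 0.00502, -0.0242 and 0.113 for numbers 1 to 4, and only the libraries numbered 4 correlated best with each other, a hint from the data, not the design. The fit with the replicate number as a block gave 156 genes, 112 higher and 44 lower, and 20 lists. Depth limits low genes: a gene without reads is bounded only at 0.0559 in Uninduced and 0.0808 in Induced libraries.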

Other observations

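The tests of T cells, of 1 receptor and of windows of fixed width were chosen after the results they bear on were seen. So were those of GC content, of scaling and of other splits for the count of genes. The tests of splits for lists and of neighbours on chromosome 11 in a window of their own width were written before.

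Immunoglobulin constant genes were named after their values were seen. Of 12 measured, 2 passed limma's threshold: Ighg1 rose from 11077 ± 441 to 16588 ± 3745 (SD, n = 4 per group; log2 fold change 0.56, adjusted p = 0.0173) and Iglc1 from 43671 ± 3962 to 57883 ± 10695 (log2 fold change 0.39, adjusted p = 0.0479). The Iglc1 call was lost under 15 settings, among them equal totals (adjusted p = 0.272). Of the fits that left out 1 library, it held only without Induced replicate 1 or 3. The Ighg1 call was lost under 6, among them without Uninduced replicate 1 (0.0622) or Induced replicate 2 (0.0962). The other 10 did not pass. In cells sorted without GL7 and FAS, Bcl6 stood at 922 ± 89.5 in Uninduced libraries, above Cd38 at 51.8 ± 11.4. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no read in any library.

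T cell receptor transcripts were abundant in all 4 Induced libraries and near 0 in the Uninduced ones. T cells in the sort would bring CD3 chains, but Cd3d, Cd3e and Cd3g together reached at most 0.0257% of Trac, and the gate required B220, which argues against T cells as the source. For 1 rearranged receptor, the other explanation tested, 100% of the alpha chain V reads in every Induced library fell in the Trav14 family, whose copies share reads, and 69.5 to 91.2% of the beta chain V reads in Trbv12-2. A second beta segment, Trbv26, was also read in every Induced library (mean 3.88 against 14.5 for Trbv12-2). Trac lay far above Trbc2 in these libraries (means 7410 and 253), and the cause of either difference was not tested. The Trav14 and Trbv12 families are used by the ovalbumin-specific OT-I and OT-II receptors, so a candidate explanation is a receptor transgene or allele in the Induced animals, which the labels do not name. If so, the groups may differ in genotype beyond the Zfp318 allele, which these data leave open for every other gene.

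Mtmr4, Rnf43 and Supt4a, neighbours on the same strand of chromosome 11, rose together. In 10000 random placements of the 98 called higher genes, a share of 0.0422 put as many in a window of 151461 bases, the width these genes span. The genes themselves set that width. In windows of fixed width the count to be matched differed. This count was the most found in any window on any chromosome, which need not hold these neighbours. It was 2 genes in 100000 bases (share 0.786), a window too narrow to hold all 3 neighbours. It was 3 in 200000 bases (0.0612), 3 in 500000 (0.24) and 4 in 1000000 (0.0498). The placements take no account of the size of a change, and chance neighbours stay open. Of the gene models 0 overlap, which argues against shared reads. The symbol 4-Sep, a date form that Sept4 takes in spreadsheets, went from 0.504 ± 1.01 to 44.5 ± 14.6 (limma adjusted p = 2.05e-05), while Hsf5, between Mtmr4 and Rnf43, stayed at 1.08 and 1.19. Coordinates came by symbol, so 4-Sep had no position and was left out of the placements. An inserted sequence, transcription that runs from 1 gene into the next, and regulation by Zfp318 may each account for the pattern and were not tested.

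Median GC content was 56.7% for genes called higher, 48.4% for genes called lower and 52.7% for the rest. With the trend of fold changes with GC content and coding length removed, the median of Glycolysis and TCA cycle genes went from 0.37 to 0.34 and both lists stayed past the threshold, which argues against the trend as their whole cause. The mtDNA-encoded median went from -1.02 to -0.40 and the list still passed camera, so the trend and a biological change cannot be told apart there, since all measured members lie at the low end of GC content. Scaling is argued against for these genes, since the largest shift it gave to the median of all genes was 0.109. A biological effect of Zfp318 stays open, as untested.

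Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many as 142 genes, the highest other giving 1. That share, 1 of 35, is the smallest this design allows, so it argues against chance for that count without excluding it. For the lists too, only the real split (1 of 35) gave as many as 20. The highest other split gave 17, and the median of the others was 4.5. With that smallest possible share, and no list call held with an estimated correlation, chance stays open for the lists. The mean log2 value of each list relative to all tested genes did not overlap between the groups for 9 of 45 lists (5 higher, 4 lower). The higher ones were T cell, Glycolysis, TCA cycle, Antioxidant defence, and Complexes II and III. The lower ones were Follicular and naive B cell, Quiescence factors, Splicing and transcription elongation, and Anti-apoptotic, which did not pass camera. The groups overlapped for the other lists past camera's threshold, among them S phase, Unfolded protein response, Memory B cell, mtDNA-encoded and both ribosomal lists. Chance gives 2.86% of lists on average over orderings, but lists can vary together. Adjusted exact permutation p-values decide nothing here, since the smallest exact p is 0.0286 and 9 such lists of 45 cannot pass.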
